A study of Mus musculus with 8 samples.

How the data were processed

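Hippocampal RNA of male mice was measured on 8 whole-transcript arrays. The dams had received clothianidin, a neonicotinoid insecticide that acts on nicotinic acetylcholine receptors, by mouth at 65 mg/kg/day, or vehicle, on postnatal days 1 to 4. Offspring were sampled at 3 or 10 weeks of age, which gives 4 groups of 2 arrays. Per the labels, 250 ng of total RNA with an integrity number above 7 was labelled with biotin for each array. The labels do not say that the arrays come from separate animals or litters. The p-values therefore measure only the spread between these samples, which may be technical.

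The deposited values are log2 intensities, 1 per transcript cluster and array, made by the authors with RMA per the submitters' processing notes, which give no version. The log2 scale was read from the values, which run from 1.57 to 19.93 in steps of 0.01. Whether the 8 arrays were normalised together is not stated. The matrix holds 22206 transcript clusters, and all were used, with no filter on dim clusters. Some named genes therefore read below the lower quartile of the arrays, where a signal above background was not shown. Symbols came from the platform annotation and were looked up in the RefSeq gene table of GRCm38.p6: 19572 clusters carry 1 symbol, 2634 carry none, and these symbols name 19505 distinct genes. No genome positions are given, since the build behind the array is not stated. The precision of each value is limited by the number of arrays, 2 per group.

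A single linear model with a mean per group was fitted to the log2 values in limma 3.58.1 under R 4.3.3, with the default empirical Bayes prior and 4 residual degrees of freedom. It gave 7 contrasts: clothianidin against vehicle at each age, the difference between those effects, their mean, and 10 against 3 weeks over all arrays, in the vehicle arrays and in the clothianidin arrays. Tests were two-sided, p-values were adjusted by the method of Benjamini and Hochberg over all clusters, and the threshold was 0.05. Errors of differences are the standard errors of this model, with 2 arrays in each group. A looser count took clusters with an unadjusted p under 0.05 and at least 1.5-fold difference.

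For 38 lists of genes (receptors, channels, hippocampal and neighbouring cell types, stress and metabolic responses) camera in limma compared each list with all other genes at a preset inter-gene correlation of 0.01, with adjustment over the 38 lists and the brightest cluster per gene. Every call was repeated with the correlation estimated from the arrays. The fry test of limma asked whether a list moves on balance one way, or in either direction. All members were measured in 6 lists, and the smallest list held 3 measured members. Genes of a list were also adjusted over the list alone, with no further adjustment over the 38 lists. With 38 lists per contrast, some lists can hold a gene past the threshold in this adjustment by chance. Such values therefore do not replace the adjustment over all clusters.

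The samples, groups, tests, lists, alternative settings and the rule for naming genes were fixed before the data were examined. The rule took, for each contrast, the 10 largest rises and the 10 largest falls among clusters past the threshold whose groups did not overlap. Where fewer passed, it filled each direction to 10 with the largest differences among those with an unadjusted p under 0.01 and no overlap, to be given as values. The condition on overlap was not applied to the difference between the exposure effects, which compares 4 groups. It added the 2 strongest members of each list described, up to 4 members past the threshold, and 10 fixed genes at both ages: Chrna4, Chrnb2, Chrna7, Chrna3, Chrna5, Bdnf, Dcx, Prox1, Ttr and Fos. Predicted genes, olfactory and vomeronasal receptors and small RNAs were counted and not named. For some lists the text names more members past the threshold than this rule allows.

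The alternative settings were an adjusted p under 0.1, the looser count, a prior that follows the mean or is robust, only the arrays of the groups compared, the replicate number as a block, array weights, clusters at or above the median level of 5.76, quantile normalisation, centring of each array on its median, the mean of all clusters of a gene, and leaving out each array in turn. The Ttr level as a covariate, and a fit without the 3 arrays with Ttr above 18, were added after seeing the data.

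The model was tested on simulated data with 22206 clusters of the same layout. For 2 against 2 arrays it called 20.0% of the clusters shifted 2-fold and 98.0% of those shifted 4-fold. For the age contrast of 4 against 4 it called 66.0% of those shifted 2-fold and all of those shifted 4-fold. It also called 8 clusters that were not shifted in the former and 13 in the latter. The simulated clusters were independent with normal errors, without the differences that many genes share between real arrays. These shares therefore need not hold for the real data. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. No columns of the matrix were left out.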

Results

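Gene expression was measured in the hippocampus of male mice at 3 and 10 weeks of age, after their dams had received clothianidin at a dose with no observed adverse effect (65 mg/kg/day) or vehicle on postnatal days 1 to 4. Each combination of age and exposure had 2 arrays, 8 in all, with 22206 transcript clusters. Array medians lay between 5.73 and 5.86 on the log2 scale. The first vehicle array at 3 weeks had the narrowest distribution, with a standard deviation of 3.14 against 3.26 to 3.39 in the other arrays. Arrays of the same group correlated at a median Pearson r of 0.988 over clusters, arrays of the same age and different exposure at 0.989, and arrays of different age at 0.981. The first principal component held 38.1% of the variance and separated the ages, and the second held 19.0%, with the first vehicle array at 3 weeks at 50.1 and the others between -29.1 and 24.0.

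The arrays also differed in genes of the choroid plexus, the secretory epithelium of the ventricles, which lies next to the hippocampus. Ttr, the thyroid hormone carrier secreted by this epithelium, read 19.16 in the second vehicle array at 3 weeks, 18.82 in the first clothianidin array at 3 weeks and 18.25 in the first clothianidin array at 10 weeks. In the other 5 arrays Ttr lay between 5.24 and 7.37. The potassium channel gene Kcnj13 read 12.02, 11.68 and 11.99 in the same 3 arrays, and the folate receptor gene Folr1 read 9.57, 9.04 and 9.46. Of the 22 measured members of the choroid plexus list other than Ttr, 18 had their 3 highest arrays in these 3, against 0.393 by chance. The 3 arrays are 1 of 2 vehicle arrays at 3 weeks and 1 of 2 clothianidin arrays at each age, while neither vehicle array at 10 weeks is among them.

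**Figure D1:**
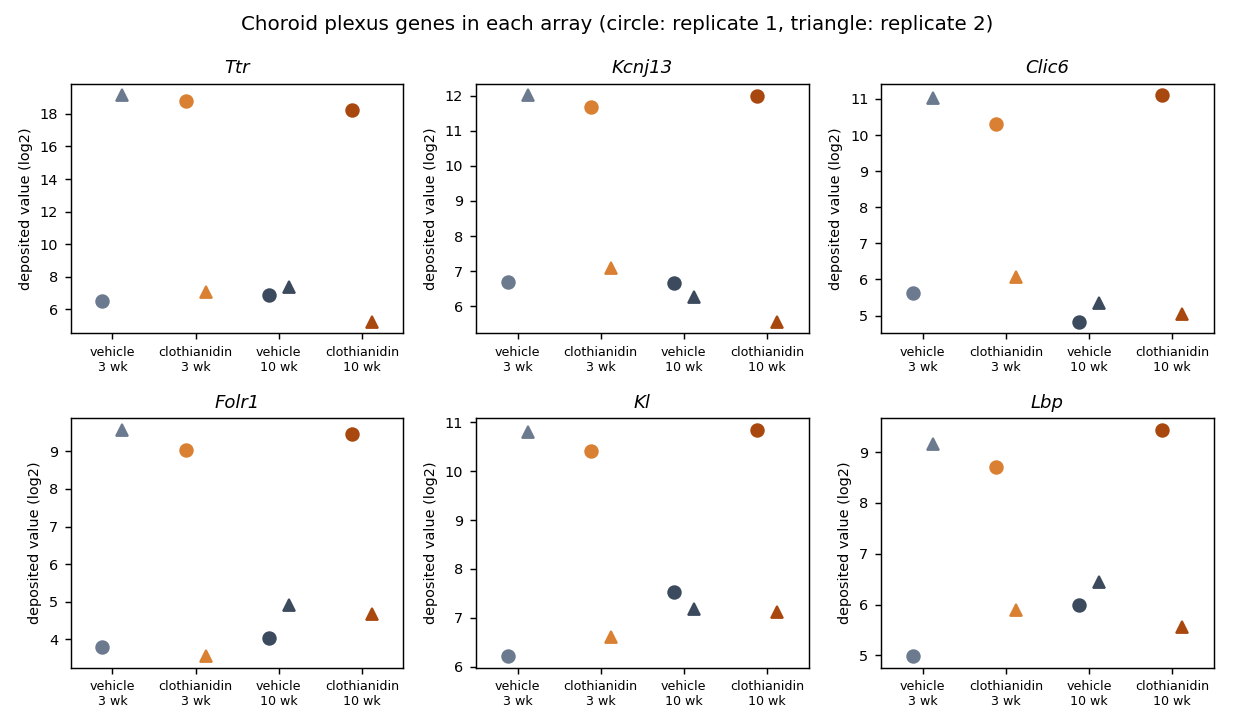
Deposited log2 values of 6 choroid plexus genes in each of the 8 arrays, by group, with circles for replicate 1 and triangles for replicate 2. Ttr lies above 18 in 3 arrays and between 5.24 and 7.37 in the other 5.

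The first comparison asked which hippocampal genes differed at 3 weeks between mice exposed to clothianidin as neonates and vehicle mice. Cd36, a fatty acid transporter and scavenger receptor, showed the largest higher value among the genes that met the naming rule: 3.74 ± 0.52 (SD, n = 2) in vehicle and 6.39 ± 0.08 (SD, n = 2) in clothianidin arrays, a log2 difference of 2.65 ± 0.42 (SE). Cdkn1a, the p21 cell cycle inhibitor, stood at 5.65 and 7.16, a difference of 1.51 ± 0.29. Among the lower values, the Y-linked translation factor gene Eif2s3y stood at 9.80 in vehicle and 8.09 in clothianidin arrays, a difference of -1.72 ± 0.28, and Dgkq, a diacylglycerol kinase, differed by -1.55. None of these genes passed the threshold over all clusters: the adjusted p in limma was 0.626 for Cd36, Eif2s3y and Dgkq and 0.846 for Cdkn1a. Adjusted over the list alone, Cdkn1a reached 0.00645 among 28 glucocorticoid response genes, and Eif2s3y reached 0.000181 among 3 genes of the sex chromosomes. These values are not adjusted over the 38 lists, where some lists can hold such a gene by chance. Both genes had also been named for their large differences, so the values are no separate support. The other members of the list of sex chromosome genes overlapped between the groups. Kdm5d read 6.17 and 6.28 in vehicle and 6.15 and 6.49 in clothianidin arrays, and Uty 9.19 and 9.81 against 9.24 and 9.01.

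The other genes named at 3 weeks are likewise values that did not pass. The unadjusted p under 0.01 that the naming rule asks for was reached by 222 clusters, where chance gives 222. The actin regulator Wipf3 differed by 1.81, followed by Sh3bgrl3, the sulfotransferase gene Sult2a2 (1.59), the DNA repair gene Fanca (1.47), the cytochrome P450 gene Cyp3a13, Hnrnpa0, Iqcf3 and the mitochondrial ribosome gene Mrpl52. Cyp3a13 differed by 1.36 ± 0.32, with an adjusted p of 0.0347 in limma when adjusted over the list alone (28 genes of xenobiotic metabolism) and 0.846 over all clusters. Lower values after clothianidin came from the X-linked genes Xlr4b (-1.54) and Xlr4c (-1.52), Cep72, Pinlyp, the keratin gene Krt20, Serpinb3c, Rsrp1 (-1.34) and the lymphocyte inhibitory receptor gene Btla (-1.32). Without the first vehicle array at 3 weeks Wipf3 differed by 0.94, Hnrnpa0 by 0.82, Xlr4b by -0.97 and Btla by -0.86, and without the first clothianidin array at 3 weeks Rsrp1 differed by -0.75.

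Nicotinic acetylcholine receptor genes, which encode the target of clothianidin, were examined in a list of 22 measured genes, 16 receptor subunits and 6 chaperones or modulators of the receptor (Lynx1, Lypd1, Lypd6, Ly6h, Ric3 and Tmem35a). At 3 weeks 12 members were higher and 10 lower after clothianidin (8 and 8 of the subunits), with a list median log2 difference of 0.05 and an adjusted camera p of 0.861 (adjusted p 0.941 with an estimated correlation). Chrna4 and Chrnb2, the subunits of the main high-affinity receptor of the brain, differed by -0.27 ± 0.52 and 0.37 ± 0.27, Chrna7 of the homomeric receptor by 0.54 ± 0.34, Chrna3 by -0.37 ± 0.28 and Chrna5 by 0.68 ± 0.44. Without the first vehicle array at 3 weeks Chrna4, Chrna7 and Chrna5 differed by 0.46, 0.02 and -0.01. The muscle subunit gene Chrnd had the largest test statistic of the list, at -1.01 ± 0.29, with an adjusted p of 0.846 in limma and 0.113 adjusted over the list alone. Chrnd read 2.17 to 3.6, below the lower quartile of every array. The subunit genes Chrna1, Chrna2, Chrna10 and Chrng also lay below that quartile in every array. At 10 weeks 11 members were higher and 11 lower (8 and 8 of the subunits), with a list median of -0.01 and an adjusted camera p of 0.945 (adjusted p 0.941 with an estimated correlation), and Chrna4, Chrnb2, Chrna7, Chrna3 and Chrna5 differed by -0.06, 0.08, 0.35, 0.25 and -0.10. No member of the list passed at either age, over all clusters or adjusted over the list alone.

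Nuclear genes of the respiratory chain, which carries out oxidative phosphorylation, were higher after clothianidin at 3 weeks in 24 of 30 cases, with a median of 0.25. Ndufa2 and Ndufa5, subunits of complex I, differed by 0.90 ± 0.35 and 0.94 ± 0.42. The list passed in camera with an adjusted p of 0.038, but not with an estimated correlation, which gave an adjusted p of 0.941, and 0 of its genes passed alone. Nor did it pass with the replicate number as a block, after quantile normalisation or among clusters at or above the median level. Without the first vehicle array at 3 weeks its median was 0.08 with an adjusted p of 0.551, and without the second clothianidin array at 3 weeks the adjusted p was 0.126. Of the fixed neuronal genes, the neurotrophin Bdnf differed by 0.98 ± 0.43, the dentate transcription factor Prox1 by 0.78 ± 0.50, the immature neuron gene Dcx by 0.41 ± 0.28 and the activity gene Fos by -0.30 ± 0.45, all with an adjusted p of 0.846 or more in limma. Without the first vehicle array at 3 weeks Bdnf differed by 0.36, Prox1 by 0.05, Fos by 0.44 and Ndufa5 by 0.31, and without the first clothianidin array Prox1 differed by 0.19 and Dcx by 0.24.

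At 3 weeks limma called 0 of the 22206 clusters past the threshold, with a lowest adjusted p of 0.626. An unadjusted p under 0.05 was reached by 1310 clusters, where 1110 would be reached by chance, and 1295 of them differed at least 1.5-fold (622 higher, 673 lower). This looser count was 762 without the first vehicle array, 2923 without the second vehicle array and 812 without the first clothianidin array at 3 weeks. The exposed and vehicle arrays did not overlap in 34.4% of the clusters, against 33.3% by chance.

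The second comparison asked which genes differed in adult mice at 10 weeks. Among the genes that met the naming rule, with an unadjusted p under 0.01 and no overlap between the groups, the largest lower value came from Fmod, a small proteoglycan that binds collagen fibrils, at 8.25 ± 0.04 (SD, n = 2) in vehicle and 5.71 ± 0.16 (SD, n = 2) in clothianidin arrays, a difference of -2.54 ± 0.55. The largest higher value under that rule came from the zinc finger gene Zfp119b, at 3.74 in vehicle and 5.68 in clothianidin arrays, a difference of 1.94 ± 0.32. Both had an adjusted p of 0.997 in limma over all clusters. Other higher values came from Spata9 (1.65), the odorant-binding protein gene Obp2a (1.14), Islr2 (1.13), Rcbtb2, Akap4, Qrsl1, the polarity kinase gene Mark2 (0.99), Mrpl23 and the lysosomal enzyme gene Gusb. Other lower values came from the phosphatase gene Ctdp1 (-1.42), the parathyroid hormone gene Pth (-1.37), Calr4, Klra9, the organic cation transporter gene Slc47a1 (-1.29), the meiotic genes Iho1 and Hormad1, Klhl1 and Clrn1. Leaving out the first vehicle array at 10 weeks brought Islr2 to 0.69 and Hormad1 to -0.80, and leaving out the second brought Klra9 to -0.77.

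Genes of the meninges, fibroblasts and collagens, the connective tissue that wraps the brain and its vessels, were lower after clothianidin at 10 weeks in 21 of 23 cases, with a median of -0.34. Fmod headed the list, followed by the GABA and taurine transporter gene Slc6a13 at -0.99 ± 0.39. The adjusted p of Fmod was 0.0152 when adjusted over the list alone, which leaves the 38 lists unadjusted. The list passed in camera with an adjusted p of 0.000203, and its adjusted p with an estimated correlation was 0.841. Without the second clothianidin array at 10 weeks the median was -0.24, the adjusted p 0.171 and the Slc6a13 difference -0.52.

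**Figure D2:**
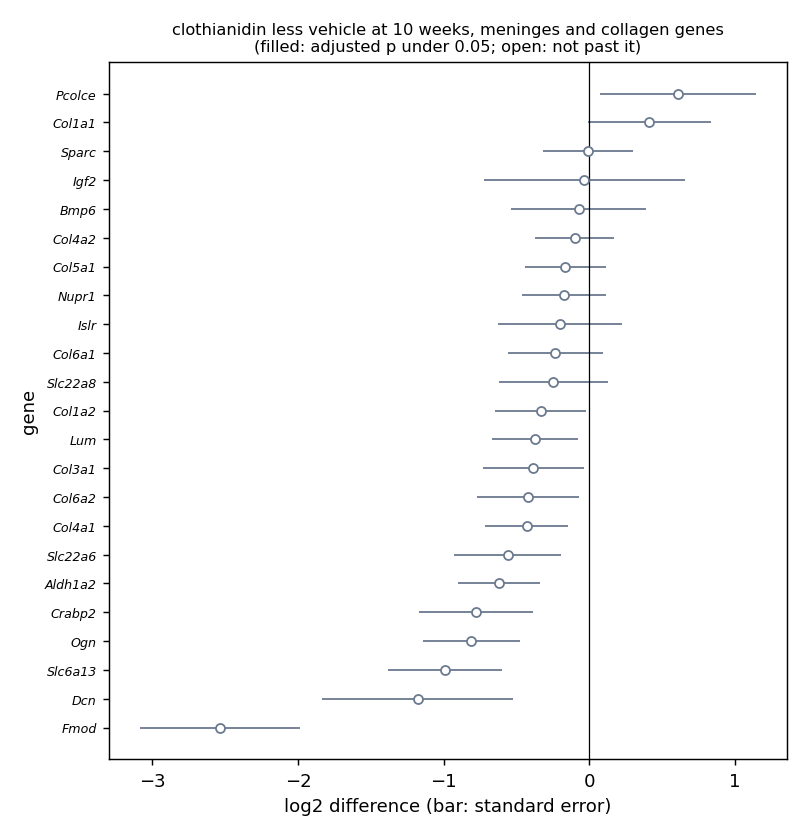
Log2 differences (clothianidin less vehicle, 10 weeks) of the 23 measured genes of the meninges, fibroblasts and collagens list, with bars for the standard error and 2 arrays per group. All points are open, as 0 genes passed the threshold over all clusters, and 21 lie below 0, with Fmod lowest at -2.54.

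Dentate granule cell genes were higher after clothianidin at 10 weeks in 14 of 16 cases, with a median of 0.39 and 0 genes past the threshold. The kinase-related gene Plk5 differed by 0.90 ± 0.32 and the tryptophan-degrading enzyme gene Tdo2 by 0.76 ± 0.40, the latter by 0.24 without the first clothianidin array at 10 weeks. The list passed in camera with an adjusted p of 0.0171, and its adjusted p with an estimated correlation was 0.941. Without the first clothianidin array at 10 weeks, where Ttr read 18.25, the median was 0.03 and the adjusted p 0.585, and with the Ttr level as a covariate the adjusted p was 0.387. It was 0.131 without the first and 0.0753 without the second vehicle array at 10 weeks, and 0.0674 after quantile normalisation.

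Choroid plexus genes were higher at 10 weeks in 21 of 23 cases, with a median of 0.89, an adjusted camera p of 0.00496 and an adjusted p of 0.941 with an estimated correlation. Ttr itself differed by 4.63 ± 4.53 and the chloride channel gene Clic6 by 2.98 ± 1.93, since only the first of the 2 clothianidin arrays carried the high values. Without that array the list median was -0.39 with an adjusted p of 0.053, and without the first vehicle array at 10 weeks the adjusted p was 0.117. At 3 weeks, with 1 array of high Ttr in each group, Ttr differed by 0.13 ± 4.53, and the list median was -0.01 (adjusted camera p 0.593, and adjusted p 0.954 with an estimated correlation).

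At 10 weeks Bdnf differed by 1.03 ± 0.43, Prox1 by 0.60 ± 0.50, Dcx by 0.06 and Fos by -0.36, each with an adjusted p of 0.997 in limma. Without the first clothianidin array at 10 weeks Bdnf differed by 0.49, and without the first vehicle array at 10 weeks Prox1 differed by 0.21. Again 0 clusters passed the threshold, with a lowest adjusted p of 0.997. An unadjusted p under 0.05 was reached by 820 clusters, fewer than the 1110 of chance, and 815 of them differed at least 1.5-fold (336 higher, 479 lower). The unadjusted p under 0.01 of the naming rule was reached by 107 clusters, where chance gives 222. Without the second vehicle array at 10 weeks 1 gene passed, Lcn2, an iron-binding protein of the acute phase response named here after its values were seen, with a difference of -5.04 and an adjusted p of 0.00504. Lcn2 read 8.04 in the first vehicle array at 10 weeks and between 2.60 and 4.17 in the other 7 arrays.

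The third comparison asked whether the exposure difference itself changed between 3 and 10 weeks. Genes were named here whether or not their groups overlapped. Among the genes that met the naming rule Cd36 had the largest negative value, -3.48 ± 0.60, since it was higher in clothianidin arrays at 3 weeks (6.39 against 3.74) and lower at 10 weeks (3.90 against 4.73). At 10 weeks its groups overlapped, with 5.4 and 4.06 in vehicle and 4.18 and 3.61 in clothianidin arrays. Cdkn1a gave -1.95 ± 0.40, Sult2a2 -1.77 and Pth -1.61, with further negative values for Hormad1 (-1.92), Clca4a, Clrn1, Itgbl1, Piwil1 and Hyal5. Ace, the angiotensin-converting enzyme gene and a member of the choroid plexus list, gave 2.40 ± 0.78, and 1.54 without the first clothianidin array at 10 weeks, where Ttr read 18.25. Eif2s3y gave 1.88 ± 0.39, with further positive values for Obp2a (2.04), Zfp976 (2.02), BC055324, Taar7f, Pramel30, Olig3 (1.71), Tmem267 and Uchl4. In limma 0 clusters passed, with a lowest adjusted p of 0.998, and 695 reached an unadjusted p under 0.05, fewer than the 1110 of chance. The unadjusted p under 0.01 of the naming rule was reached by 112 clusters, where chance gives 222. Of the lists, choroid plexus passed in camera, with 20 of 23 genes higher, a median of 1.04 and an adjusted p of 0.0292 (adjusted p of 0.96 with an estimated correlation). After quantile normalisation this list did not pass. Without the first clothianidin array at 10 weeks the median was -0.30, and without the second vehicle array at 3 weeks it was -0.18. It did not pass without the second clothianidin array at 3 weeks (median -0.12), the first vehicle array (1.06) or the second vehicle array (1.27) at 10 weeks. Without the second vehicle array at 10 weeks Lcn2 again passed alone, with a difference of -5.57 and an adjusted p of 0.0211.

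The mean of the exposure differences over both ages, with 4 arrays on each side, was asked for effects shared by the ages. Bdnf, the activity-dependent neurotrophin, was higher in both clothianidin arrays than in both vehicle arrays at each age, with a mean difference of 1.00 ± 0.30. The synaptic scaffold gene Grasp gave 1.01 ± 0.29, the fibroblast growth factor receptor gene Fgfr1 0.87 and Zfp119b 1.17 ± 0.22, with Slc35a4, Qrsl1, Polr2l, Islr2, Apcdd1 and Rap2b between 0.87 and 0.98. Lower values came from Rsrp1 (-1.23 ± 0.26), the autophagy gene Atg16l2 (-1.15), Pinlyp (-1.02), the serine synthesis enzyme gene Psph (-0.94), Mroh8, Zfp82, Meikin, Zfp72, the taste receptor gene Tas2r120 and Ccdc172. Atg16l2 stood at -0.67 without the first vehicle array at 3 weeks. Each had an adjusted p of 0.774 in limma, which called 0 clusters, while 1371 reached an unadjusted p under 0.05, where chance gives 1110. The unadjusted p under 0.01 of the naming rule was reached by 241 clusters, where chance gives 222. Adjusted over the list alone, Bdnf reached 0.121 among the neurotrophins, other growth factors and their receptors. The clock repressor gene Nr1d1, with a mean difference of 0.72 ± 0.19, reached 0.0491 among 19 circadian genes. Neither value is adjusted over the 38 lists, where some lists can hold a gene past the threshold by chance.

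Over both ages, the meninges, fibroblasts and collagens list was lower in 18 of 23 genes (median -0.22, adjusted camera p 0.0121, and adjusted p 0.753 with an estimated correlation). Fmod stood at -1.55 ± 0.39, with an adjusted p of 0.045 when adjusted over the list alone, and the retinoic acid enzyme gene Aldh1a2 at -0.55 ± 0.20. The Fmod value came mostly from 10 weeks (-2.54), while at 3 weeks (-0.56) the groups overlapped, with 8.14 and 7.62 in vehicle and 6.19 and 8.45 in clothianidin arrays. Without the first clothianidin array at 3 weeks its difference was 0.57 at that age and -0.98 over both ages. The list did not pass without the second clothianidin array (adjusted p 0.151) or without the first vehicle array (0.0581) at 10 weeks. Dentate granule cell genes were higher in 13 of 16 cases (median 0.31, adjusted camera p 0.0356, and adjusted p 0.753 with an estimated correlation), led by Tdo2 at 0.77 ± 0.28 (0.51 without the first clothianidin array at 10 weeks) and Pdzd2 at 0.40. This call ended with the Ttr level as a covariate (adjusted p 0.133), without the first vehicle array at 3 weeks (median 0.05, adjusted p 0.829) and without the first clothianidin array at 10 weeks (0.188). It also ended without the first vehicle array (0.0901) or the second vehicle array (0.0501) at 10 weeks. Of 34 ways to split the 8 arrays into 4 and 4, 29 gave at least 2 lists past the threshold.

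The exposure differences at the 2 ages were compared over all clusters, which are not independent replicates. They correlated at r = 0.175 (Spearman's rho 0.190), and 56.5% of the clusters had the same sign. Among clusters of the looser counts at both ages, 24 were higher at both (9.41 by chance), 30 lower at both (14.5 by chance) and 20 opposite (23.6 by chance). Bdnf, Grasp, Fgfr1, Qrsl1 and Slc35a4 were among the former, and Rsrp1, Psph, Zfp82, Tas2r120 and Ccdc172 among those lower at both. Without the first vehicle array at 3 weeks r was -0.0129, and without the first clothianidin array at 10 weeks it was 0.0716. The counts of shared clusters were not repeated without these arrays.

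**Figure D3:**
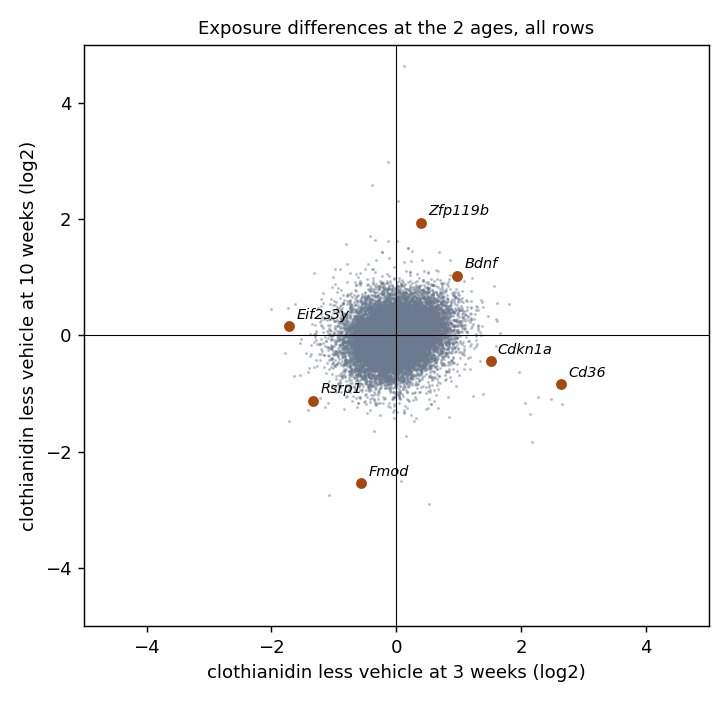
Log2 differences, clothianidin less vehicle, at 3 weeks (horizontal) and 10 weeks (vertical), 1 point per transcript cluster and 2 arrays per group. The cloud is centred near 0 with r = 0.175, and the 7 labelled genes include Bdnf at 0.98 and 1.03 and Cd36 at 2.65 and -0.84.

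The last comparison asked how the hippocampus differed between 10 and 3 weeks, over both exposures with 4 arrays per age. Several of the largest falls came from genes of oligodendrocytes, the myelin-forming cells. Gelsolin (Gsn), an actin-severing protein, fell by 3.17 ± 0.22 on the log2 scale (8.97-fold, adjusted p 0.000236 in limma). Ugt8a, the enzyme that makes the myelin lipid galactosylceramide, fell by 2.62 ± 0.25 (adjusted p 0.00099), and Enpp6, a choline phosphodiesterase of newly formed oligodendrocytes, fell by 2.48 ± 0.24 (adjusted p 0.00092). Il33, a nuclear alarmin cytokine, rose by 2.27 ± 0.20 (4.81-fold, adjusted p 0.000831), and the neurotrophin receptor gene Ngfr rose by 2.02 ± 0.20 (adjusted p 0.00121).

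Of the 28 measured oligodendrocyte and myelin genes, 12 fell, 4 rose and 12 did not pass, and adjusted over the list alone 12 fell and 4 rose as well. Beside Ugt8a and Enpp6, those that fell included the tight junction gene Cldn11 (-2.37 ± 0.28), the myelin adhesion gene Mag (-2.17 ± 0.27), Tspan2, Cnp, Mog, Mobp, Fa2h, Mal, Opalin and Mbp (-1.14 ± 0.24). Ndrg1 (1.77 ± 0.21), Bcas1 (0.93), the node of Ranvier gene Hapln2 (0.92) and Adamtsl4 (0.70) rose. The list median was -0.38, with an adjusted camera p of 0.000667 and an adjusted p of 0.692 with an estimated correlation. Oligodendrocyte precursor genes were lower in 14 of 16 cases, with a median of -0.33, and Gpr17, a receptor of committed precursors, fell by 1.76 ± 0.29 (adjusted p 0.00737), the only member past the threshold over all clusters or adjusted over the list alone. The precursor list had an adjusted camera p of 0.0287, and an adjusted p of 0.692 with an estimated correlation. Its adjusted p was 0.138, 0.073 and 0.064 without the second vehicle array at 3 weeks, the first clothianidin array at 3 weeks and the second clothianidin array at 10 weeks. With the Ttr level as a covariate its adjusted p was 0.0845, while the myelin list still passed, with 0.00431.

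**Figure D4:**
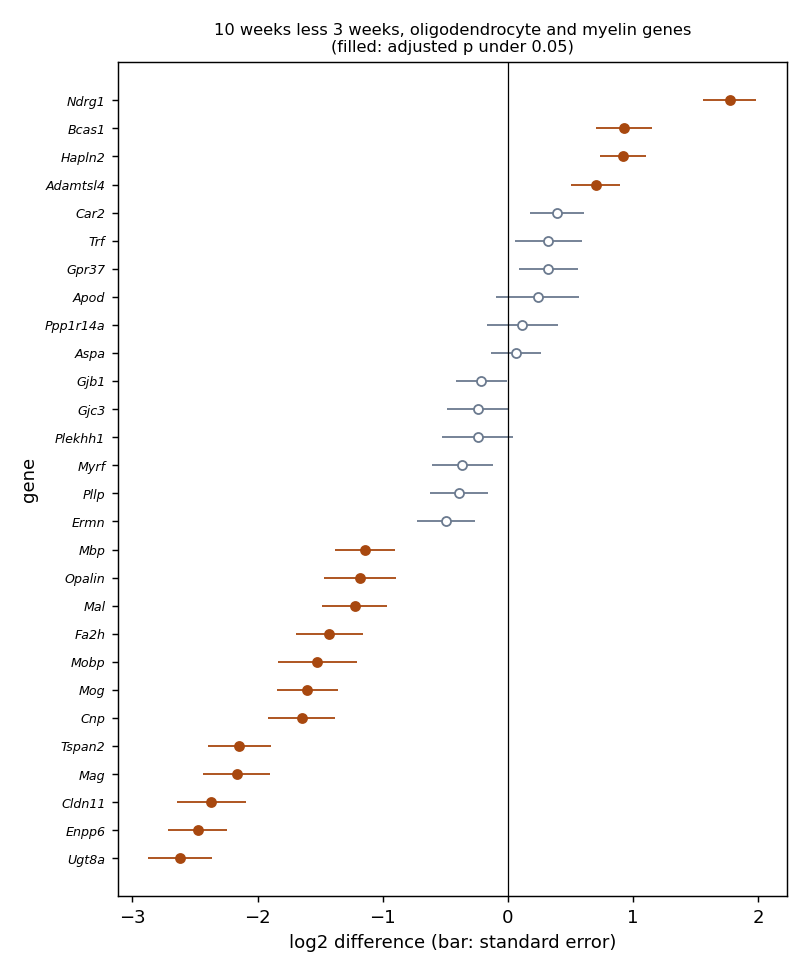
Log2 differences, 10 less 3 weeks over both exposures, of the 28 measured oligodendrocyte and myelin genes, with bars for the standard error and 4 arrays per age. Filled points passed an adjusted p of 0.05: 12 lie below 0, with Ugt8a lowest at -2.62, and 4 lie above 0, with Ndrg1 highest at 1.77.

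Some genes of newborn neurons and of dividing cells fell between 3 and 10 weeks, while most members of both lists did not pass. Among 17 immature granule neuron genes, Dcx (-0.96 ± 0.20, adjusted p 0.0156), the calcium-binding protein gene Calb2 (-0.92) and Draxin (-0.77) fell and the transcription factor gene Neurod2 (0.87) rose, with the same counts adjusted over the list alone. The list median was -0.29 with an adjusted camera p of 0.0359, and an adjusted p of 0.692 with an estimated correlation. It did not pass without the second vehicle array at 3 weeks (adjusted p 0.0914), the first clothianidin array at 3 weeks (0.073) or the second clothianidin array at 10 weeks (0.117), nor with the Ttr level as a covariate (0.0845). Of 30 cell division genes, 5 fell and 0 rose: Mki67, the Ki-67 proliferation marker (-1.51 ± 0.24, adjusted p 0.00654), the replication helicase gene Mcm5 (-1.21), and the spindle genes Tpx2 (-1.26), Kif20a (-1.03) and Aurka (-0.81). Adjusted over the list alone 6 fell and 1 rose, and the list as a whole had an adjusted camera p of 0.0581.

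Members of several neuronal lists that did not pass as a whole changed with age. Of the 22 genes of the nicotinic receptor list, the subunit gene Chrnb2 rose by 0.68 ± 0.19 (adjusted p 0.0459 in limma) and Chrna3 by 0.70 ± 0.20 (adjusted p 0.0476), while 0 passed adjusted over the list alone and the list had an adjusted camera p of 0.68. Of 26 genes of potassium and sodium channels and their auxiliary proteins, the potassium channel genes Kcnj9 (1.39 ± 0.26) and Kcna1 (0.77) and the sodium channel genes Scn3a (0.71) and Scn1a (0.70) rose and Scn8a (-0.87) fell. Adjusted over the list alone 9 rose and 1 fell, with an adjusted camera p of 0.0581 for the list. The perineuronal net gene Hapln4 rose by 1.62 ± 0.25, while Hapln1 (-0.87) and the aggrecan-cleaving enzyme gene Adamts4 (-1.55) fell. The clock genes Arntl (1.20 ± 0.18), Cry2 (1.07) and Per1 (0.81) rose, and so did the activity genes Fos (1.37 ± 0.32), Nr4a1 (0.85), Egr4 (0.77) and Fosb (0.69), with Ier2 (-1.07) falling.

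Further rises came from Ms4a4c (2.20), Jade2 (1.95), Spata2 (1.90), Mllt1 (1.87), the cilium gene Mks1 (1.83), the organic anion transporter gene Slco1a6 (1.82) and the potassium channel gene Kcns3 (1.79). Further falls came from the ubiquitin ligase gene Rnf122 (-3.15 ± 0.29), Tma16 (-2.12), Dmrta1 (-2.05) and the cilium gene Bbs5 (-1.93). Jade2 did not pass without the first clothianidin array at 3 weeks, the second vehicle array at 10 weeks or the second clothianidin array at 10 weeks. Choroid plexus genes were lower at 10 weeks in 22 of 23 cases (median -0.73, adjusted camera p 0.0122, and adjusted p 0.766 with an estimated correlation), with Ttr above 18 in 2 arrays at 3 weeks and 1 at 10 weeks. In this list Wfdc2 alone passed, falling by 1.25 ± 0.24 (adjusted p 0.0119), and with the Ttr level as a covariate the list median was -0.05 and its adjusted p 0.638. Without the second vehicle array at 3 weeks, the first clothianidin array at 3 weeks and the second clothianidin array at 10 weeks the list median was -0.12, -0.32 and -0.04, none past the threshold. The meninges, fibroblasts and collagens list was lower in 18 of 23 genes (median -0.33, adjusted camera p 0.0223, and adjusted p 0.692 with an estimated correlation), with the matrix protein gene Sparc falling by 1.31 ± 0.22 (adjusted p 0.00737). That list did not pass without the second clothianidin array at 3 weeks (adjusted p 0.0628) or at 10 weeks (0.117), and it still passed with the Ttr level as a covariate (0.0216).

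In all, 2490 clusters passed between the ages, 1415 higher and 1075 lower at 10 weeks, and the 2 ages did not overlap in 19.7% of the clusters, against 2.86% by chance. After centring each array on its median the balance turned, to 992 higher and 1283 lower, and after quantile normalisation it was 983 and 1067. Without the second clothianidin array at 10 weeks it was 301 and 327, while clusters at or above the median level were 891 higher and 252 lower. The count was 1255 without the first vehicle array at 3 weeks, 717 and 949 without the first and second clothianidin arrays at 3 weeks, 1357 and 1085 without the first and second vehicle arrays at 10 weeks, and 816 and 628 without the first and second clothianidin arrays at 10 weeks. Of 34 ways to split the 8 arrays into 4 and 4, only the split by age gave as many clusters, but 19 gave at least the 5 lists that passed between the ages. In a fit without the 3 arrays of high Ttr, which leaves 1 residual degree of freedom, 0 passed.

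Within each exposure Gsn fell and Il33 rose with age. Gsn had an age difference of -3.42 in vehicle arrays (adjusted p 0.0043 in limma), and Il33 one of 2.57 in clothianidin arrays (adjusted p 0.00837). In vehicle arrays 26 clusters rose and 44 fell, and in clothianidin arrays 49 rose and 76 fell, with 34 past the threshold in both, all in the same direction. If the calls were independent 0.394 would be shared, but both contrasts use 1 estimate of the spread per cluster. Cd36 fell by 2.49 with age in the clothianidin arrays (adjusted p 0.0363). Oligodendrocyte and myelin genes passed in camera in both, with medians of -0.33 in vehicle arrays (adjusted p 0.000194, and adjusted p 0.694 with an estimated correlation) and -0.41 in clothianidin arrays (adjusted p 0.00199, and adjusted p 0.817 with an estimated correlation). The vehicle call on that list ended without the second vehicle array at 3 weeks (median -0.17, adjusted p 0.218). The choroid plexus list passed in the vehicle arrays (median -1.15, adjusted p 0.000194, and adjusted p 0.694 with an estimated correlation), where the second vehicle array at 3 weeks held the high Ttr, and without that array its median was 0.16. In the clothianidin arrays the immature granule neuron list (median -0.40, adjusted p 0.0257, and adjusted p 0.707 with an estimated correlation) and the meninges, fibroblasts and collagens list (median -0.38, adjusted p 0.00199, and adjusted p 0.707 with an estimated correlation) passed. Without the second clothianidin array at 10 weeks both had an adjusted p of 0.0724, and without the first clothianidin array at 3 weeks the immature granule neuron list had 0.0776. The vehicle count was 17 without the first vehicle array at 3 weeks, 0 without the second vehicle array at 3 weeks or the first at 10 weeks, 2 without the second vehicle array at 10 weeks, and 1 without any 1 of the clothianidin arrays. The clothianidin count was 0 without any 1 of the clothianidin arrays and 16 without either vehicle array at 10 weeks.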

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

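The tests of choroid plexus genes, of the agreement between the ages and of the Ttr covariate were chosen only after the results were seen, as was the use of the planned estimated correlation to weigh an exposure effect on the meninges list, while the counts of other splits and the test of a varying amount of meninges were planned.

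Choroid plexus genes differed between the exposure effects at the 2 ages, by a test of that difference itself: the list median was 1.04 higher at 10 than at 3 weeks (20 of 23 genes, adjusted camera p 0.0292, and adjusted p 0.96 with an estimated correlation). After quantile normalisation the list did not pass. At 10 weeks 0 of the 23 members were higher in both clothianidin arrays than in both vehicle arrays, where chance gives 3.83. The values of each array had been seen before and the members vary together. The count therefore describes these arrays and is no independent test of 1 exposure effect in every exposed sample. Of the 22 members other than Ttr, 18 had their 3 highest values in the 3 arrays of high Ttr, so a candidate explanation is that these 3 samples held choroid plexus tissue, which no sort or gate would remove from a dissected hippocampus. Ttr reached 19.16, and Kcnj13, Clic6 and Folr1 were high in the same 3 arrays. Of the 23 members, 9 lie at or above the median cluster level in the other 5 arrays and 0 are in another list, and an exposure effect on the amount of tissue taken with the hippocampus stays open as untested.

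Exposure differences at 3 and 10 weeks correlated over clusters at r = 0.175. Their covariance was 0.0224 with a jackknife standard error over arrays of 0.0288, so the value is smaller than its error and leaves an exposure effect shared by both ages open. The value rests on the first vehicle array at 3 weeks: without it the covariance was -0.00167, and without the second vehicle array it was 0.0464. That the array stands apart for a reason other than exposure stays open, because the correlation of 0.244 between the second less the first vehicle array at 3 weeks and the exposure difference at 10 weeks restates the covariance without that array and is no separate test.

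Meninges and collagen genes were lower after clothianidin at 10 weeks, 21 of 23 genes with a median of -0.34, led by Fmod. With the Ttr level as a covariate the median was -0.36 and the adjusted camera p 7.19e-05 at the preset correlation, so this adjustment did not remove the difference. It does not settle the choroid plexus content of the arrays as a cause. Ttr lay either above 18 or at most at 7.37, so its slope rests on the 3 arrays of high Ttr, and the fit leaves 3 residual degrees of freedom. The difference was smaller without the second clothianidin array at 10 weeks. A varying amount of meninges in the samples stays open: within groups, 62.0% of the members moved the same way between the 2 arrays, with a median of 58.3% and a 95th percentile of 64.1% over random lists. An exposure effect could not be settled either, since the adjusted p with an estimated correlation was 0.841.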

How the results depend on the processing

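The Ttr covariate and the fit without the 3 arrays of high Ttr were added after seeing the data, and all other settings were planned. All 2490 age calls kept their direction in every setting that tested them, and 1774 of the 1803 called with the replicate number as a block, 1796 of the 2050 after quantile normalisation and 1967 of the 2270 with the Ttr covariate were among them. The exposure contrasts stayed at 0 clusters in limma under every setting except those named here, and a trend or robust prior moved no count by more than 1.5 times. Over all settings the named genes kept direction and side of the threshold in 2339 cases, lost the threshold in 395 and turned direction in 19, all of them genes that had not passed. Many cases keep their direction by construction, so the counts do not measure robustness. Another prior or block leaves the difference unchanged, as does leaving out an array outside the contrast. Genes named because their groups did not overlap cannot turn when 1 array is left out. With 2 arrays per group the median standard error of an exposure difference was 0.308, which limits what could be called. Where the cause is not given by a setting's own construction (fewer arrays, fewer clusters, another threshold), the cause was not tested.

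At an adjusted p under 0.1 the age, vehicle age and clothianidin age counts were 4389, 736 and 715. With an unadjusted p under 0.05 and at least 1.5-fold, 1295 passed at 3 weeks, 815 at 10 weeks, 695 for the difference between the ages, 696 over both ages, 4577 for age, 4202 for vehicle age and 3920 for clothianidin age. With an estimated correlation 0 lists passed in all 7 comparisons. In the directional fry test 8 passed for age and 0 in the other 6, and in the mixed fry test 32, 21 and 15 passed for age, vehicle age and clothianidin age and 0 in the 4 exposure comparisons. With only the arrays of the 2 groups vehicle age gave 0 clusters.

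With the replicate number as a block vehicle age gave 1 (Gsn), clothianidin age 17 and the lists at 3 weeks 0. Deviations of the groups by replicate number correlated between -0.267 and 0.138. These deviations include the differences in choroid plexus genes between arrays of the same group. The correlations therefore cannot settle whether arrays of the same replicate number belong together, which the labels do not say. Array weights gave 1 (Gsn) for vehicle age and 658 for clothianidin age. Both arrays of a group received the same weight, so this setting weighted groups and could not single out an array. The weights at 3 and 10 weeks were 0.776 and 0.907 for vehicle and 1.16 and 1.22 for clothianidin arrays. Clusters at or above the median level gave looser counts of 711 and 315 at 3 and 10 weeks, 1143, 34 and 23 for age, vehicle age and clothianidin age, and 0, 9, 5 and 5 lists at 3 weeks and for these 3. After quantile normalisation Chrnb2 at 10 weeks was -0.0112, and lists numbered 0 at 3 weeks, 0 for the difference, 1 over both ages and 5 each for vehicle age and clothianidin age.

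With the Ttr covariate Chrna4 and Dcx at 10 weeks were 0.34 and -0.0594, vehicle age gave 11, the agreement r was 0.0609, and lists numbered 1, 1, 2 and 1 at 10 weeks, over both ages, for age and for vehicle age. Without the 3 arrays of high Ttr (1 residual degree of freedom) Chrna4, Dcx and Ttr at 10 weeks were 0.76, -0.17 and -1.88, the age, vehicle age and clothianidin age counts were 0, 0 and 0, and r was 0.0503. Lists then numbered 5 at 3 weeks, 9 at 10 weeks, 5 for the difference, 6 over both ages, 1 for age, 1 for vehicle age and 8 for clothianidin age, and the choroid plexus median was -0.39 at 10 weeks and -0.51 for the difference.

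Leaving out each array, with the lone array assumed to vary like the other groups, gave ranges of 628 to 2550 for age, 0 to 17 for vehicle age, 0 to 150 for clothianidin age, 0 to 1 at 10 weeks and for the difference (Lcn2, without the second vehicle array at 10 weeks), 762 to 2923 for the looser count at 3 weeks and -0.0129 to 0.247 for r, the lowest without the first vehicle array at 3 weeks. Lists ranged from 0 to 7 at 3 weeks, 3 to 5 at 10 weeks, 0 to 6 for the difference, 0 to 10 over both ages, 1 to 9 for age, 1 to 7 for vehicle age and 1 to 10 for clothianidin age. The choroid plexus median ranged from -0.39 to 2.18 at 10 weeks and from -0.30 to 2.62 for the difference. At 3 weeks Chrna4 ranged from -1.0 to 0.46, Chrna5 from -0.01 to 1.36, Chrna7 from 0.02 to 1.06, Chrnb2 from 0.27 to 0.48, Chrna3 from -0.42 to -0.31, Bdnf from 0.36 to 1.59, Prox1 from 0.05 to 1.51, Dcx from 0.24 to 0.57, Fos from -1.04 to 0.44 and Ttr from -6.21 to 6.47. At 10 weeks Chrna4 ranged from -0.88 to 0.76, Chrna5 from -0.61 to 0.42, Chrnb2 from -0.10 to 0.25, Chrna7 from 0.21 to 0.48, Chrna3 from 0.03 to 0.47, Bdnf from 0.49 to 1.57, Prox1 from 0.21 to 1.00, Fos from -0.45 to -0.27, Dcx from -0.17 to 0.28 and Ttr from -1.88 to 11.14.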

Other observations

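The splits of the arrays and the lists given here were planned before the results were seen, while the genes that differ between arrays of 1 group were chosen after their values were seen.

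Members of further lists changed with age. Of 20 monoamine receptor genes, the serotonin receptor genes Htr1a (0.84 ± 0.19) and Htr5a (0.66) and the dopamine receptor gene Drd2 (0.88 ± 0.22) rose between 3 and 10 weeks and 0 fell, with the same counts adjusted over the list alone, and of 15 genes of the GABA-A receptor list the subunit genes Gabra2 (0.68) and Gabrb2 (0.65) rose and 0 fell. The innate immune genes C4b (0.95 ± 0.19) and Ccl2 (0.85), the antigen-presenting gene H2-K1 (0.77) and the complement gene C1qb (0.97) rose, while Ccl3 (-0.81) and the interferon-induced gene Rsad2 (-0.75) fell. Of 19 genes of cholesterol synthesis and its control Cyp51 (-1.08 ± 0.19) and Hmgcs1 (-0.82) fell and 0 rose, and adjusted over the list alone 3 fell. The glucocorticoid receptor gene Nr3c1 (-0.73) and the corticotropin-releasing hormone receptor gene Crhr1 (-0.68) fell, while the glucocorticoid-induced gene Klf15 (0.97 ± 0.21) rose. The phospholipid receptor gene Lpar1 fell by 1.25 ± 0.19, and the stress response genes Ddit3 (1.24) and Trib3 (-0.81) went opposite ways. None of these lists passed in camera between the ages (adjusted p 0.317, 0.991, 0.991 and 0.61 for monoamine receptors, GABA-A receptor, inflammation and microglia, 0.0656 for cholesterol synthesis, 0.568 for glucocorticoid response, 0.439 for neural stem cells and 0.135 for the unfolded protein response).

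Markers of regions that border the hippocampus were read as well. At 10 against 3 weeks Drd2, Penk (0.87), Rarb (0.68), Actn2 (0.69) and Scn4b (0.74) rose among 18 striatum and amygdala genes, with a list median of 0.50 and an adjusted camera p of 0.0656 (adjusted p 0.692 with an estimated correlation). Of 17 neocortex genes Deptor (1.19 ± 0.28), Fezf2 (0.84), Lamp5 (0.79) and Whrn (0.78) rose and Pamr1 (-1.17) fell, with an adjusted camera p of 0.286 for the list. Of 20 thalamus genes Gbx2 (0.83) and Ntng1 (1.02) rose and Calb2 (-0.92) fell, with an adjusted camera p of 0.61. Gbx2 read 2.56 to 3.65, below the lower quartile of every array.

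Several genes were far apart between the 2 arrays of 1 group. In the vehicle group at 10 weeks Lcn2 read 8.04 and 3.77 and Fstl1, a secreted glycoprotein, read 6.46 and 9.36, and Cbln1, a secreted synapse organiser, read 7.82 and 5.49. In the vehicle group at 3 weeks Cbln1 read 8.75 and 5.74. In the array with the high Lcn2 the neutrophil genes S100a8 and S100a9 read 4.19 and 5.77, against 2.84 to 4.27 and 4.60 to 5.66 in the other 7. Eif2s3y read 9.77 and 9.83 in the vehicle arrays at 3 weeks and 7.68 to 8.30 in the other 6 arrays. Differences of more than 1 log2 unit between the 2 arrays were seen in 1759 clusters of the vehicle group and 903 of the clothianidin group at 3 weeks, and in 1289 and 801 at 10 weeks.

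Splits of the 8 arrays into 4 and 4 were fitted with the other factor as a covariate, 34 for each comparison. For age, 1 of the 34 gave as many clusters as the real split, the real one itself with 2905 in this additive model, and the highest of the others gave 2. That share, 1 of 34, is the smallest this test can give. The other splits leave the age difference in the residual spread, which lowers their counts. The count sets the split by age apart among these splits but does not exclude chance. For the 5 gene lists between the ages, 19 of 34 splits gave at least as many, and the highest of the others gave 14, so chance is not excluded there either. For exposure over both ages 1371 clusters reached an unadjusted p under 0.05 in the main limma model, where chance gives 1110. In the additive model the real split gave 0 clusters past the threshold, and the highest of the others gave 0. With 0 in the real split, all 34 splits had to give at least as many, so this count tests nothing. For the 2 lists of exposure over both ages, 29 of 34 splits gave at least as many and the highest of the others gave 12, so chance is not excluded.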
